A study of Arabidopsis thaliana with 6 samples.

How the data were processed

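Foliar RNA of 3 Arabidopsis samples that express Avr2 from the 35S promoter and of 3 samples of the wild type Col-0 was hybridised to 1-colour Affymetrix Arabidopsis arrays. Each sample pooled 10 plants grown for 4 weeks, per the labels, and the series' design text states that the samples came from 3 independent experiments. Total RNA was labelled with biotin in a 1-cycle protocol, per the labels' protocols. The deposited values are linear intensity values per probe set, made with MAS5 per the submitters' processing notes. The MAS5 version, its scaling target and any filter are not given in the sources used here. Each array holds 22810 probe sets, of which 64 are controls. All 6 sample columns of the table were used.

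The deposited values were not at a common level. The mean after trimming 2% at both ends ran from 65.1 to 109 and the median from 19.1 to 35.1 between arrays. The design fixed before the data were examined had assumed values scaled by MAS5 and no further normalization. Because the arrays were not scaled, quantile normalization between arrays was used for the main values, a choice listed beforehand as an alternative and taken before any fit. The fit on the values as deposited, which is the one written in the design, is given as an alternative. Values under the 10th percentile of the table (1.17 on the linear scale) were set to it, log2 was taken, and a probe set was tested when its mean over the 6 arrays lay above the 25th percentile of the probe sets that are not controls. This left 17059 probe sets. Differences are Avr2 minus Col-0 and were tested two-sided with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A probe set at 2-fold is one with a log2 difference of at least 1 in size and an unadjusted p under 0.05, a count not controlled for multiple tests. The number of arrays, 3 per group, limits the precision of every value.

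Probe sets were named through the platform's annotation, updated by gene identifier to a gene table of assembly TAIR10.1. Of the 22810 probe sets, 13513 had 1 gene, 503 had several and 8730 had none in the table used here. Probe sets with several genes or none were tested and counted but not named. Only 75 of the 471 list members written beforehand had a named probe set, so 11 of 28 lists fixed before the data were examined had the 3 tested members needed. The other lists fixed beforehand, salicylic acid defence among them, were not tested. After the annotation had been seen, and before any gene's value was looked at, 33 further lists were written from the genes it names, and they are called added lists. An added list written by symbol can hold a namesake. The symbol POR, for example, belongs in the table to AT4G39920, a tubulin-folding cofactor, and it stayed in the list of nuclear photosynthesis genes as written. Lists were tested with camera at a preset correlation of 0.01 between genes, on the brightest probe set of each gene against all 9402 genes tested. Adjustment was made separately over the lists fixed beforehand and over the added lists. Values adjusted over a list alone come from limma refitted on these 9402 genes, whose p values differ from those of the main fit. Camera with a correlation estimated from the data was run beside it, as was fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes.

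The genes named were chosen by a rule fixed before the data were examined, among probe sets with exactly 1 gene. Up to 12 per direction that passed the adjusted threshold without overlap between groups were to be named. Where fewer passed, the list was filled to 6 per direction with the smallest unadjusted p among genes with a log2 difference of at least 1 in size and no overlap. In each list up to 4 members with the smallest p could be named. PR1, PR2, PR5, PDF1.2A, FRK1, RD21A, XCP1, XCP2, AALP, CTB3 and SAG12 were always to be named where measured. Of these 11, PDF1.2A and CTB3 had a named probe set. Avr2 itself has no named probe set here, so the transgene could not be used to check the labels.

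Samples carry the numbers 1 to 3 in both groups. The design text says that each replication held plants of both kinds, and the labels do not say that equal numbers mark the same experiment. The fit with the number as a block is therefore an alternative only. The alternatives tried were the values as deposited, shifting to a common median, scaling to a common trimmed mean, no floor, a higher floor, other filters, no intensity trend, array weights, leaving out each array or each number, 1 probe set per gene and a minimum fold. Array weights were estimated gene by gene because the default estimate did not converge. They were 4.23, 0.672 and 0.303 for Avr2 replicates 1 to 3, so a weighted Avr2 mean rests mostly on Avr2 replicate 1. After the data had been seen, scaling to a common trimmed mean and the removal of a gene length trend were added. For the latter, each array's deviation from the mean of the arrays was fitted by loess (span 0.5) on log2 gene length and the fit was subtracted. Lengths are those of the genes in the gene table and were found for 99.8% of the tested probe sets with 1 gene. Figures were drawn with matplotlib 3.10.9.

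The procedure was tested on data simulated for this comparison with independent noise, using 17059 probe sets of which 200 were changed. At 3 against 3 arrays it called 11% of the 4-fold changes and 0% of the 2-fold changes at the adjusted threshold, with 0 false calls. The 2-fold count with unadjusted p took in 89% of the 4-fold and 49% of the 2-fold changes. With no simulated effect, 564 probe sets reached that 2-fold count and 0 lists were called. Because the simulated genes vary independently, the latter cannot test false calls among genes that vary together. Other splits of the real arrays called up to 5 added lists. A simulated shift of 0.5 in the extended protease list gave an adjusted p of 0.234 with camera.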

Results

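Transcript levels were measured in leaves of Arabidopsis thaliana plants that express Avr2, a secreted effector of the tomato leaf mould fungus Cladosporium fulvum that inhibits papain-like cysteine proteases, and in leaves of the wild type Col-0. Each group had 3 arrays, 1 per sample of 10 plants at 4 weeks. The deposited medians per array ran from 19.1 to 35.1 intensity units, and values below are log2 of the quantile-normalized intensity. Mean correlations with the other arrays were between 0.902 and 0.923 for 5 arrays and 0.859 for Avr2 replicate 3. The comparison asks how expression of Avr2 alters the leaf transcriptome. The samples hold no transgenic plants without Avr2, so effects of transformation or of the insertion cannot be told apart from those of Avr2.

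In Avr2 leaves the papain-like cysteine proteases, the protein class that Avr2 binds, were called higher as a list. The photosynthesis list, with 5 of its 28 written members tested, was called lower. Among the added lists, autophagy genes, pathogen- and salicylic acid-inducible genes and plastid-encoded photosynthesis subunits were called higher. Jasmonate-responsive genes, UDP-glycosyltransferases, subtilases and nuclear-encoded photosynthesis genes were called lower. No single probe set passed the adjusted threshold, and none of these list calls held with an estimated correlation between members. That setting called no list at all, so its losses are no sign by themselves that members vary together. The call of the list of papain-like cysteine proteases ended in 3 of 6 fits that left out 1 array, with adjusted p up to 0.264, and on the values as deposited, the fit first planned (0.140). Without Avr2 replicate 3 the medians fell short of a call at -0.14 for photosynthesis (adjusted p = 0.291) and -0.14 for subtilases (0.472), as did that of the pathogen- and salicylic acid-inducible list without Col-0 replicate 3, at 0.01 (0.681). The closest single gene was AT3G16670, at 10.5-fold lower signal in Avr2.

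For single probe sets, 0 of 17059 passed with limma, with a smallest adjusted p of 0.0607. An unadjusted p under 0.05 was reached by 636 probe sets, 362 higher and 274 lower in Avr2, where 852.95 would be reached with no effect. At 2-fold, 200 probe sets were higher and 160 lower. On the values as deposited this split was 701 higher and 26 lower, with the median of all tested probe sets at 0.35 log2 in place of 0.03. The 360 probe sets at 2-fold compare with 564 in data simulated with no effect. The simulated noise was independent between genes and its SDs were drawn at random, so 564 is no exact null for these arrays. Without Avr2 replicate 2 the counts were 357 higher and 950 lower, and the count lower was 242 without Avr2 replicate 1, 102 without Avr2 replicate 3 and 97 without Col-0 replicate 3. Without Col-0 replicate 3, 1 probe set passed the adjusted threshold, that of AT1G21520. Groups did not overlap for 1695 probe sets, or 9.94%, where chance gives 10%.

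The 6 genes named with higher signal in Avr2 did not pass the adjusted threshold. AT1G21520 had 6.58 ± 1.77 in Col-0 and 10.28 ± 0.18 in Avr2 (SD, n = 3), a log2 difference of 3.70. AT1G43910 had 5.86 ± 1.06 and 8.50 ± 0.03, a 6.24-fold difference. AT5G39520 differed by 4.04-fold, from 5.62 ± 0.63 to 7.64 ± 0.32. All 3 had an adjusted p of 0.761. AT2G29070 was at 3.21-fold, AT4G23880 at 2.98-fold and AT2G38640 at 2.69-fold, each with an adjusted p of 0.961. The wide spread of AT1G21520 and AT1G43910 in Col-0 came from Col-0 replicate 3, at 4.54 and 4.64, while the other Col-0 arrays lay between 6.42 and 7.72.

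The 6 genes named with lower signal were led by AT3G16670, at 8.52 ± 0.70 in Col-0 and 5.13 ± 0.16 in Avr2 (SD, n = 3), with an adjusted p of 0.0607. It passed in 7 of 22 alternatives, among them arrays shifted to a common median (0.0499), a higher floor (0.0240), array weights (0.0034) and, chosen after the data were seen, only probe sets with 1 gene of known length (0.0139). Over the 22 its adjusted p ran from 0.0034 to 0.724. The lowest came with array weights, where the Avr2 mean rests mostly on Avr2 replicate 1. AT3G05730 missed the threshold at 3.16-fold lower signal (adjusted p = 0.813), from 9.29 ± 0.43 to 7.63 ± 0.45. The mitochondrial gene nad4, which encodes a subunit of respiratory complex I, stood at 8.87 ± 0.16 and 7.72 ± 0.17, 2.23-fold lower. AT4G17480 was 6.59-fold lower but close to the floor in Avr2, with values between 0.81 and 1.66. AT3G24190 and AT1G51580 were 2.46-fold and 2.76-fold lower. These last 4 genes had an adjusted p of 0.961.

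**Figure D1:**
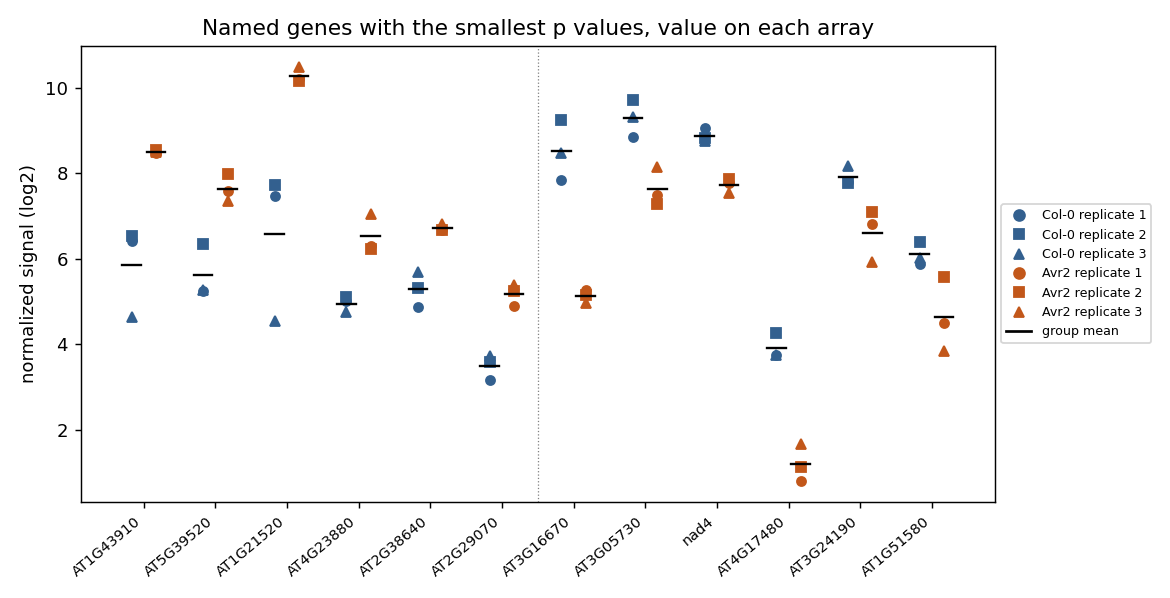
Normalized log2 signal (vertical axis) on each of the 6 arrays for the 12 genes named by smallest p, with points for arrays and bars for group means. The 3 Avr2 values of AT3G16670 lie between 4.96 and 5.28 and its Col-0 values between 7.85 and 9.25.

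Papain-like cysteine proteases were called higher in Avr2 as a list fixed beforehand, with 7 of 8 tested members higher and a median log2 difference of 0.42 (camera, adjusted p = 0.0357). The call was lost in camera with an estimated correlation (adjusted p = 0.351). That estimate was -0.016, below the preset 0.01, so the loss is no sign of members varying together. By smallest p the first members were the cathepsin B-like genes. AT1G02300 was 1.66-fold higher, from 5.58 ± 0.17 to 6.31 ± 0.15, AT1G02305 was 1.43-fold higher and AT4G01610 (CTB3) was 1.42-fold higher, all 3 without overlap between groups. AT3G19390, chosen after its values were seen, was 2.23-fold higher, dim and with overlap between groups. The member with lower signal was AT1G06260, at 2.35-fold lower, dim in both groups and also without overlap. In the extended list of the family 12 of 13 members were higher, with a median of 0.50 (adjusted p = 0.00851, and adjusted p = 0.586 with an estimated correlation). No member of either list passed by itself, neither over all probe sets nor adjusted over the list alone. The call of the list fixed beforehand ended without Col-0 replicate 1 (adjusted p = 0.228), without Avr2 replicate 1 (0.264) or without Avr2 replicate 2 (0.237), with medians of 0.27, 0.22 and 0.44, and that of the extended list ended without Col-0 replicate 1 (median 0.33, 0.0701) or Avr2 replicate 1 (median 0.48, 0.0763). The list fixed beforehand passed in 12 of 25 alternatives and the extended list in 19, and the former was not called on the values as deposited (median 0.73, 0.140), with arrays shifted to a common median (0.46, 0.228) or scaled to a common trimmed mean (0.38, 0.0732), with no intensity trend (0.42, 0.158) or with the gene length trend removed (0.39, 0.0634). Nor was it called with the replicate number as a block (0.42, 0.103), where the extended list was (0.0135).

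Other proteases and their inhibitors gave a mixed picture. Subtilases, secreted serine proteases, were lower in 7 of 7 members with a median of -0.70 (adjusted p = 0.00767, and adjusted p = 0.928 with an estimated correlation). SBTI1.1 was 3.92-fold lower and SBT3.3 was 3.38-fold lower, with SDs in Avr2 of 2.60 and 2.82 because both were at the floor on Avr2 replicate 3. These folds depend on the floor. With the floor at the 30th percentile the log2 differences were -0.99 and -0.78, against -1.97 and -1.76. ARA12 was 1.62-fold lower, from 8.82 ± 0.13 to 8.12 ± 0.81. The log2 differences without Avr2 replicate 3 were -0.48 for SBTI1.1, -0.28 for SBT3.3 and -0.23 for ARA12, and without Avr2 replicate 2 that of SBT3.3 was -3.02. On average the members lay at -2.56 on Avr2 replicate 3 and between -0.08 and 1.13 on the other arrays, relative to their mean over all 6. Without Avr2 replicate 3 the median was -0.14 (adjusted p = 0.472), and without Col-0 replicate 1 the call also ended (adjusted p = 0.0575). The median was -1.20 without Col-0 replicate 2, -1.22 without Col-0 replicate 3 and -1.92 without Avr2 replicate 2. The list passed in 16 of 25 alternatives, and not among probe sets above the median level (0.160), with no filter on dim probe sets (0.0577), with array weights (0.0639) or with the gene length trend removed and the third Avr2 array left out (median -0.18, 0.431). The list of protease inhibitors and vacuolar processing enzymes was not called, with a median of -0.07 over 7 members (adjusted p = 0.802), and its cystatin AT5G05110 was 1.55-fold higher, from 6.81 ± 0.12 to 7.44 ± 0.17.

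Autophagy genes were higher in Avr2 in 11 of 11 members, with a median of 0.54 (adjusted p = 0.00245, and adjusted p = 0.652 with an estimated correlation). Relative to their mean over all 6 arrays, the members averaged -0.31, 0.02 and -0.42 on Col-0 replicates 1 to 3. On Avr2 replicates 1 to 3 they averaged 0.15, -0.02 and 0.57, so the groups overlapped on average and Avr2 replicate 3 was highest. AT5G66930 was 1.75-fold higher, from 5.66 ± 0.38 to 6.46 ± 0.32. ATG3, which conjugates ATG8 to lipid, was 1.49-fold higher. Of the ATG8 genes, which encode the ubiquitin-like proteins of the autophagosome membrane, ATG8F was 1.29-fold higher, without overlap between groups, and ATG8H had 5.54 in Col-0 and 6.13 in Avr2, with overlap and a log2 difference of 0.37 without Avr2 replicate 3. The list stayed called without each array in turn, with a median of 0.30 without Avr2 replicate 3 (adjusted p = 0.0326) and 0.34 without Col-0 replicate 3, and the call ended when both samples numbered 3 were left out (median 0.21, adjusted p = 0.233). With array weights, where the Avr2 mean rests mostly on Avr2 replicate 1, the median was 0.25 and the list stayed called (adjusted p = 0.0130).

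Pathogen- and salicylic acid-inducible genes were higher in 13 of 18 members with a median of 0.54 (adjusted p = 0.00851, and adjusted p = 0.928 with an estimated correlation). Beside AT1G21520, the cytochrome P450 gene CYP71B23 was 2.37-fold higher, from 6.13 ± 0.32 to 7.38 ± 0.14, AT5G22530 had 3.23 in Col-0 and 4.72 in Avr2, and SAG101, which encodes a lipase-like partner of EDS1, was 1.74-fold higher. AT1G21520 (0.00255) and CYP71B23 (0.0140) passed when adjusted over the list alone, an added list. The list was low on Col-0 replicate 3, where its members lay at -1.08 on average, and its median was 0.01 without that array (adjusted p = 0.681). The call also ended without Avr2 replicate 2 (0.0507) or Avr2 replicate 3 (0.110), with medians of 0.42 and 0.33. With array weights the median was 0.026 (adjusted p = 0.612), without both samples numbered 3 it was -0.10 (0.861), and the list passed in 17 of 25 alternatives.

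Jasmonate-responsive genes were lower in 16 of 20 members, with a median of -0.41 (adjusted p = 0.00305, and adjusted p = 0.411 with an estimated correlation). ORA47, a transcription factor gene of the jasmonate response, was 3.27-fold lower, from 6.05 ± 1.60 to 4.34 ± 0.15, with 7.86 on Col-0 replicate 3 and a log2 difference of -0.79 without that array, and the jacalin-related lectin gene JAL33 was 2.42-fold lower. AT5G05600 was 2.08-fold lower, with a log2 difference of -0.68 without Col-0 replicate 3. PDF1.2, a defensin gene and marker of jasmonate and ethylene signalling, was at 8.45 ± 1.13 and 7.73 ± 0.91, a difference within the spread of each group. The call held without each array in turn, with adjusted p up to 0.0326 and a median of -0.22 without Avr2 replicate 3. It ended without both samples numbered 2 (adjusted p = 0.126) and with array weights (median -0.25, adjusted p = 0.0639), and without both numbered 3 the median was 0.0027. Pattern-triggered immunity genes (median -0.08 over 6, adjusted p = 0.729) and the jasmonate-ethylene defence list (median -0.07 over 3, adjusted p = 0.802) were not called, nor were the elicitor-inducible genes of an added list (median -0.05 over 23, adjusted p = 0.780). The jasmonate-ethylene list was called lower without both samples numbered 3 (median -1.65, adjusted p = 0.0399), and its median was -0.96 without Col-0 replicate 3 (0.191) and -0.79 without Avr2 replicate 3 (0.672). EFR, the receptor for bacterial elongation factor Tu, was 1.63-fold lower.

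Photosynthesis genes of the nucleus were called lower. In the list fixed beforehand 4 of 5 members were lower with a median of -0.52 (adjusted p = 0.0283, and adjusted p = 0.351 with an estimated correlation). Only these 5 of the 28 members written were tested, among them LHCB4.1, LHCB4.2, LHCB4.3 and RCA. LHCB4.1, an antenna protein gene of photosystem II, was 1.44-fold lower, from 12.84 ± 0.05 to 12.31 ± 0.66, and RCA, the Rubisco activase gene, was 1.75-fold lower, from 12.65 ± 0.01 to 11.84 ± 1.29. Without Avr2 replicate 3 their log2 differences were -0.16 and -0.073, and that of RCA was -1.27 without Avr2 replicate 2. Over 34 nuclear-encoded genes of photosynthesis and chlorophyll synthesis 22 were lower, with a median of -0.14 (adjusted p = 0.00305, and adjusted p = 0.407 with an estimated correlation). On the values as deposited the median of this list was 0.11, below the median of all probe sets there. Both lists were low on Avr2 replicate 3, at -0.75 and -0.38, and without that array the adjusted p was 0.291 for the list fixed beforehand and 0.110 for the longer one, with medians of -0.14 and -0.07. The median of the list fixed beforehand was -0.31 without Col-0 replicate 3. That list passed in 17 of 25 alternatives, and not with no filter on dim probe sets (0.185), with no intensity trend (0.158) or with array weights (median -0.18, 0.110).

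Plastid-encoded photosynthesis subunits were called higher, with 28 of 43 genes higher and a median of 0.12 (adjusted p = 0.0127, and adjusted p = 0.928 with an estimated correlation). Adjusted over the list alone, an added list, ndhH (0.0444), atpH (0.0475) and psbB (0.0475) passed. These values come from the limma fit on 1 probe set per gene and lie close to the threshold. In the main limma fit the unadjusted p values were 0.00134, 0.00310 and 0.00464. The gene ndhH was 2.89-fold higher, from 5.72 ± 0.38 to 7.25 ± 0.47. The ATP synthase gene atpH was 1.68-fold and psbB, for the CP47 protein of photosystem II, 2.16-fold higher. The call ended without Col-0 replicate 1 (median 0.04, adjusted p = 0.533) or Avr2 replicate 1 (median 0.07, adjusted p = 0.0540), and also with arrays shifted to a common median (0.10, adjusted p = 0.217) or scaled to a common trimmed mean (0.02, adjusted p = 0.607). The median was 0.25 without Avr2 replicate 2 and 0.08 without Avr2 replicate 3. The call was lost with no intensity trend (adjusted p = 0.0765), and with the gene length trend removed the median was 0.039 (adjusted p = 0.0421), the genes having a median length of 477 bases. The median of all probe sets tested in that setting was 0.043, so the typical member was not higher than other genes there.

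UDP-glycosyltransferases, which attach sugars to hormones and secondary metabolites, were lower in 18 of 30 members with a median of -0.28 (adjusted p = 0.00943, and adjusted p = 0.407 with an estimated correlation). UGT84A3 was 1.95-fold lower, UGT88A1 1.67-fold lower, from 10.01 ± 0.27 to 9.27 ± 0.71, and UGT78D1 1.62-fold lower, while UGT85A5 was 1.57-fold higher, all 4 with overlap between groups. Without Avr2 replicate 3 the log2 differences were -0.52 for UGT84A3, -0.34 for UGT88A1 and -0.29 for UGT78D1, against -0.96, -0.74 and -0.70 with it, and that of UGT85A5 went from 0.65 to 0.39 without Col-0 replicate 2. Without Avr2 replicate 3 the list median was -0.22 (adjusted p = 0.112), and without Avr2 replicate 1 it was -0.17. The call also ended with no filter on dim probe sets (median -0.071, 0.0789), with array weights (0.0789) and without both samples numbered 2 (0.0617) or 3 (0.459).

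**Figure D2:**
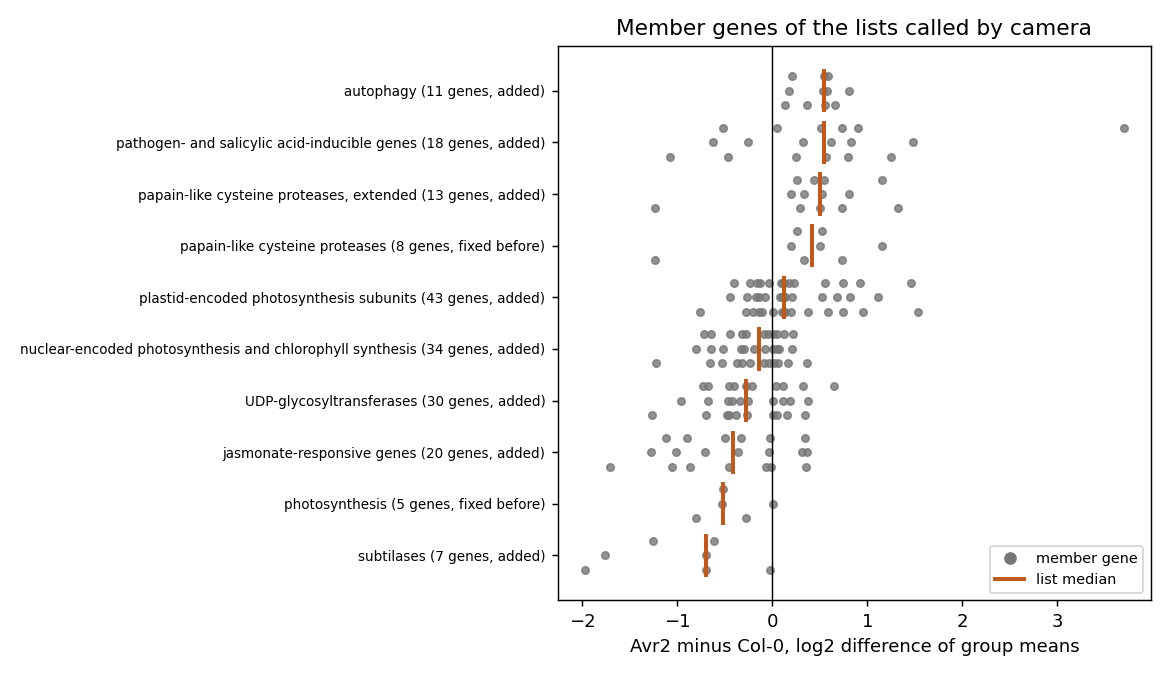
Log2 difference between the group means, Avr2 minus Col-0 (horizontal axis), of each member gene (points) of the 10 lists called by camera, with the list median as a bar. On these quantile-normalized values all 11 autophagy genes lie above 0 and all 7 subtilases below it.

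The other lists fixed beforehand, 9 in number, had medians between -0.29 and 0.19 and adjusted p between 0.729 and 0.941, and none of their members passed when adjusted over the list alone. Endoplasmic reticulum folding genes had a median of -0.16, and their member ATERDJ3B was 1.42-fold higher. Phenylpropanoid and anthocyanin genes had a median of -0.29, with UGT78D2 1.37-fold lower and its log2 difference between -0.80 and -0.27 without single Col-0 arrays. Medians were 0.10 for expansins and xyloglucan endotransglucosylases, 0.19 for auxin response and -0.0048 for abscisic acid and drought, and in these last 2 lists the median and the test differed in sign. The abscisic acid and drought list was called higher without Col-0 replicate 3 (median 0.75, adjusted p = 0.00452). Its member COR15B was at 1.60-fold, and between 0.27 and 1.39 log2 without single Col-0 arrays. The phenylpropanoid list was called lower without Col-0 replicate 1 (median -0.77, adjusted p = 0.00263). Both calls used camera at the preset correlation of 0.01. In the fit on all arrays, the estimated correlation between members was 0.764 for abscisic acid and drought and 0.906 for phenylpropanoids. With it, camera gave both lists an adjusted p of 0.838 in that fit, and neither call was tested with it. The 3 reference genes had a median of 0.16, with PEX4 at 8.21 ± 0.36 and 8.45 ± 0.58.

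The array's own controls differed between the groups in places. The 3' minus 5' log2 signal was 2.06 ± 0.17 in Col-0 and 1.61 ± 0.21 in Avr2 for actin, and 0.67 ± 0.20 and 0.17 ± 0.42 for ubiquitin (SD, n = 3), both without overlap between groups. For GAPDH it was 0.10 ± 0.09 and 0.09 ± 0.11. In another set of control probe sets, the group differences of the 3' and the 5' probe set were 0.15 and 0.23 for actin, -0.41 and -0.15 for GAPDH and -0.42 and -0.17 for ubiquitin. A difference in RNA or labelling between the groups was not separated from an effect of Avr2. Gene length moved with the arrays as well. The deviation of Avr2 replicate 3 from the mean of the other 5 arrays had a Spearman correlation of -0.45 with gene length across 9480 probe sets, which are not independent replicates, while Col-0 replicate 3 had 0.34 and Avr2 replicate 2 had 0.39. With Avr2 replicate 3 left out of the mean, the last 2 were 0.25 and 0.29, and Col-0 replicate 2 had -0.28 in place of -0.12. The difference between the groups had a correlation of -0.20 with gene length, and of 0.10 without Avr2 replicate 3.

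**Figure D3:**
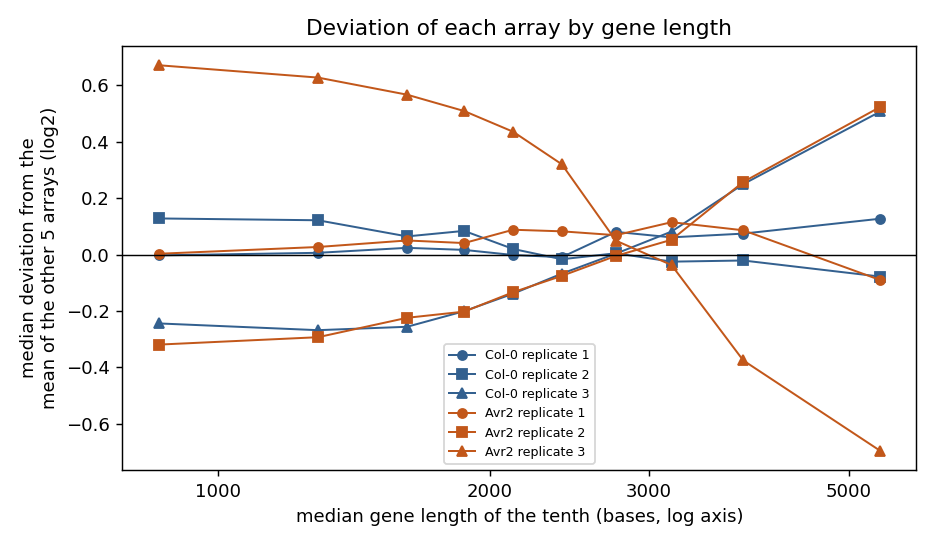
Median log2 deviation of each array from the mean of the other 5 (vertical axis) for 10 classes of genes ordered by length (horizontal axis, log scale, in bases). Avr2 replicate 3 runs from 0.67 in the shortest class to -0.70 in the longest.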

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

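Scaling to a common trimmed mean, the restriction to genes of known length, the removal of the gene length trend with or without the third Avr2 array, and the added lists were chosen only after the result or the annotation was seen, and the other alternatives were fixed in advance. Signal over background limits the dim genes most, with a median SD within groups of 1.07 log2 in the dimmest 10% of probe sets and 0.315 in the brightest 10%. Among values of named genes under an alternative, 1150 kept direction and side of the threshold, 15 passed it newly and 4 turned direction. No named gene passed in the main fit, so the side kept was that of no call. Many were also chosen for groups that do not overlap, which makes a turn unlikely when an array is left out. The counts for genes are therefore no measure of robustness. Among values of gene lists, 367 kept both, 72 lost the call in the same direction, 3 gained it in the same direction and 56 turned direction, and gains or losses that came with a turn are counted among these 56. The cause was not tested except where stated. Pattern-triggered immunity and auxin response had too few members for a value among probe sets above the median level, and nad4 had no gene length.

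Sample numbers showed no sign of pairing. Deviations from the group means correlated at -0.12, -0.23 and -0.31 between samples numbered 1, 2 and 3, and no Col-0 sample correlated best with the Avr2 sample of its own number. Within groups, the gene length trends of equal numbers were opposite in sign. They were -0.06 and 0.14, -0.27 and 0.44, and 0.29 and -0.46 (Spearman, Col-0 and Avr2). The correlations of deviations therefore cannot show that equal numbers are unpaired. With the replicate number as a block, 0 probe sets passed (smallest adjusted p 0.167), 176 were higher and 167 lower at 2-fold, 1 list fixed beforehand and 9 added lists were called, and the papain-like cysteine proteases were at 0.42 with an adjusted p of 0.103.

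As deposited, with no normalization between arrays, 701 probe sets were higher and 26 lower at 2-fold and 1 list fixed beforehand was called. Medians then carry the shift of 0.35 of all probe sets: 0.73 for papain-like cysteine proteases (adjusted p = 0.140), 0.15 for pattern-triggered immunity, 0.31 for jasmonate-ethylene defence, 0.31 for protease inhibitors and vacuolar processing enzymes, 0.10 for endoplasmic reticulum folding, 0.38 for abscisic acid and drought, 0.033 for phenylpropanoids, 0.19 for elicitor-inducible genes and 0.11 for nuclear-encoded photosynthesis genes. With arrays shifted to a common median, 1 probe set changed, 1 list fixed beforehand was called, and medians were 0.46 for papain-like cysteine proteases (adjusted p = 0.228), 0.035 for jasmonate-ethylene defence, 0.035 for protease inhibitors and 0.11 for abscisic acid and drought. With arrays scaled to a common trimmed mean, 1 list fixed beforehand was called, with 0.38 for papain-like cysteine proteases (adjusted p = 0.0732) and 0.027 for abscisic acid and drought.

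With the floor at the 30th percentile 1 probe set changed, and expansins were at -0.093. With no filter on dim probe sets, 315 were higher and 250 lower at 2-fold and 1 list fixed beforehand was called, with photosynthesis at -0.52 (adjusted p = 0.185). Among probe sets above the median level, 70 were higher and 90 lower, with expansins at -0.21 and elicitor-inducible genes at 0.21. With no intensity trend 0 lists fixed beforehand were called, with papain-like cysteine proteases at 0.42 and photosynthesis at -0.52, both with an adjusted p of 0.158. An adjusted threshold of 0.10 and 1 probe set per gene each gave 1 changed probe set. Camera with an estimated correlation and fry each called 0 lists fixed beforehand and 0 added lists, where medians of 0.42 and -0.52 are by construction as before and adjusted p was 0.0542 and 0.873 with fry.

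With array weights, 12 probe sets changed, 9 higher and 3 lower, 375 were higher and 421 lower at 2-fold, 1 list fixed beforehand and 4 added lists were called, and 2 list members changed. Because Avr2 replicate 1 had by far the largest weight, these counts compare mostly that array with Col-0. Medians were -0.18 for photosynthesis (adjusted p = 0.110), 0.011 for protease inhibitors, 0.10 for endoplasmic reticulum folding, 0.55 for abscisic acid and drought, 0.38 for phenylpropanoids and -5.0e-05 for expansins. Among genes of known length, where fewer probe sets were tested, 1 changed and 122 were higher and 80 lower at 2-fold. With the gene length trend removed these counts were 1, 124 and 83, 1 list fixed beforehand was called, and papain-like cysteine proteases were at 0.39 (adjusted p = 0.0634). With the gene length trend removed and without the third Avr2 array, 1 probe set changed, 84 were higher and 52 lower, 1 list fixed beforehand and 4 added lists were called, and medians were -0.11 for photosynthesis (adjusted p = 0.571), 0.040 for protease inhibitors, 0.067 for endoplasmic reticulum folding, 0.41 for abscisic acid and drought, 0.26 for phenylpropanoids, -0.051 for expansins, 0.0098 for elicitor-inducible genes and -0.044 for PEX4.

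Leaving out each array, or both samples of a number, gave 0 to 7 changed probe sets, 130 to 518 higher and 97 to 1003 lower at 2-fold, 1 to 3 lists fixed beforehand, 4 to 9 added lists and 0 to 2 changed list members. The 7 changed probe sets came without both samples numbered 3, and the 1003 lower ones without both numbered 2. The lists called were not always those of the main fit. Of its 8 added calls, 2 were kept without both samples numbered 3 and 4 without Avr2 replicate 3. Without Col-0 replicate 1 or without both numbered 2, 5 were kept, and all 8 without Col-0 replicate 2. Of its 2 calls of lists fixed beforehand, 1 or 2 were kept. Medians ran from 0.21 to 0.47 for papain-like cysteine proteases, -0.69 to -0.14 for photosynthesis, -0.48 to 0.14 for pattern-triggered immunity, -1.65 to 0.12 for jasmonate-ethylene defence, -0.25 to 0.093 for protease inhibitors, -0.53 to 0.22 for endoplasmic reticulum folding, -0.62 to 1.18 for abscisic acid and drought, -1.02 to 0.64 for phenylpropanoids, -0.25 to 0.41 for expansins, -0.17 to 0.39 for auxin response and -0.018 to 0.32 for reference genes. Among added lists they ran from -0.10 to 0.79 for pathogen- and salicylic acid-inducible genes, -0.23 to 0.078 for elicitor-inducible genes and -0.64 to 0.0027 for jasmonate-responsive genes. The log2 difference of PDF1.2 ran from -1.82 to 0.025 and that of PEX4 from -0.27 to 0.65. Over 25 alternatives adjusted p ran from 0.00644 to 0.474 for papain-like cysteine proteases and from 0.000541 to 0.873 for photosynthesis, and autophagy passed in 22 of 25, jasmonate-responsive genes in 21 and nuclear-encoded photosynthesis genes in 20.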

Other observations

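The tests of other splits, of gene length, of 3' to 5' signal, of members varying together and of Col-0 replicate 3 were chosen only after the result was seen, while those of signal level and of dim members were written before it. Genes of cold, drought and late embryogenesis had higher values in Avr2 in 12 of 16 members, with a median log2 difference of 0.27 (camera, adjusted p = 0.0506, not called, and adjusted p = 0.634 with an estimated correlation). Among genes of known length its adjusted p was 0.0491, and with the gene length trend removed the median was 0.18 (0.173). COR27, a cold-regulated gene, was at 3.57 ± 0.19 in Col-0 and 4.59 ± 1.23 in Avr2 (SD, n = 3), with 3.70, 4.07 and 5.99 on Avr2 replicates 1 to 3. DI19, a drought-induced gene, was at 9.96 ± 0.22 and 10.33 ± 0.09. All 5 markers of the stomatal lineage and trichomes had lower values, with a median of -0.29 (adjusted p = 0.110, not called, and adjusted p = 0.634 with an estimated correlation). With the gene length trend removed the list was called (median -0.37, adjusted p = 0.0421), and with Avr2 replicate 3 also left out it was not (0.0572). Of the transcription factors of stomatal development, FMA was at 4.84 ± 0.18 and 4.43 ± 0.16, and SPCH had 2.87, 4.48 and 1.48 on the Avr2 arrays and between 3.39 and 4.15 in Col-0.

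Organelle genes other than those of photosynthesis were not called as lists. Plastid-encoded ribosomal protein and RNA polymerase genes had a median of -0.14, with 13 of 20 lower (adjusted p = 0.110), and rpoA was at 9.89 ± 0.35 in Col-0 and 9.25 ± 0.55 in Avr2 (SD, n = 3). Over 13 mitochondrion-encoded genes the median was 0.04 while the mean was -0.08 and the test pointed down (adjusted p = 0.503). Only nad4 passed there when adjusted over the list alone (0.0110), and it did not pass over all probe sets in any of 19 alternatives, with adjusted p from 0.0957 to 1. Median and test also differed in sign for serine carboxypeptidase-like proteins and secondary wall and vascular markers, and mean and test for beta-glucosidases, serine carboxypeptidase-like proteins, endoplasmic reticulum quality control and endoglucanases. Over all 25 added lists that were not called, medians lay between -0.29 and 0.28. In the cytochrome P450 71B list CYP71B23 passed when adjusted over the list alone (0.0171).

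The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The count of changed probe sets says nothing here, because it was 0 in the real split and any split is then at least as large, as all 10 were with a highest other count of 0. The real split gave 360 probe sets at 2-fold, 4 of 10 splits gave as many, and the highest other count was 984, for Col-0 replicates 1 and 3 with Avr2 replicate 2 against the rest, which points to a structure of the arrays that does not follow the groups. That split goes with the sign of the gene length trend. The Spearman correlations were 0.06, 0.34 and 0.39 on its arrays, and -0.12, -0.01 and -0.45 on Col-0 replicate 2, Avr2 replicate 1 and Avr2 replicate 3. With Avr2 replicate 3 left out of the mean, Col-0 replicate 1 had -0.10. The real split called 2 lists fixed beforehand, 5 of 10 splits called as many, and the highest other count was 3. It called 2 lists fixed beforehand, 5 of 10 splits called as many, and the highest other count was 3. The real split called 8 added lists, which no other of the 10 splits reached, and the highest other count was 5.

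Avr2 replicate 3 stood apart from the other arrays, with an array weight of 0.303 against 4.23 for Avr2 replicate 1. Its deviation correlated with gene length at -0.446 (Spearman, across genes, which are not independent replicates), and its short genes were high and its long genes low. Gene length as the whole difference is argued against, since removal of the trend brought its mean correlation with the other arrays from 0.855 to 0.873, while the others then had 0.905 to 0.922. RNA degraded from the 5' end would raise the 3' minus 5' signal of all 3 control transcripts. In the first set of control probe sets given above, this signal was highest on this array for 1 of 3, GAPDH, and lowest for ubiquitin, at -0.31. A bias with signal level (correlation -0.175) stays open, and no biological explanation was tested because the labels give none for a single array.

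The extended papain-like protease list and the autophagy list were higher in Avr2. With the gene length trend removed their medians were 0.46 and 0.47 and both stayed called, which argues against length as the whole cause. Dim members near the floor are argued against as the whole cause as well. The 5 protease members above the median level of the tested probe sets were all higher with a median of 0.50. Above the lower median level of all probe sets the median was 0.33 (adjusted p = 0.00491), and all 11 autophagy members lay above both levels. The size of the protease difference did depend on the floor. With the floor at the 30th percentile the extended protease median was 0.31 (camera, adjusted p = 0.0135). With no filter on dim probe sets it was 0.39 (0.0260). Members that vary together between arrays stay open, with an estimated correlation of 0.074 in the protease list and 0.407 in the autophagy list and a smaller adjusted p of 0.586, a value that is no sign of joint variation by itself, since it was 0.407 for UDP-glycosyltransferases at an estimated correlation of -0.013. An effect of Avr2 on these genes may be present and was not separated from such variation with 3 arrays per group.

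The pathogen- and salicylic acid-inducible list was higher in Avr2. Gene length is argued against as the whole cause, as the median was 0.44 with the trend removed and the list stayed called. Members that vary together between arrays stay open, since the estimated correlation was 0.458 and the list was not called with it (camera, adjusted p = 0.928). Low values on Col-0 replicate 3 are a candidate explanation, since the median was 0.0092 without that array. AT1G21520 kept a log2 difference of 2.71 without it (adjusted p = 0.0496), so that this explanation does not cover every member. A lower defence state of that sample's plants and a response to Avr2 were not tested against each other.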
